A study of Mus musculus with 18 samples.

How the data were processed

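The labels describe RNA from salivary glands of 12-week-old C57BL/6J mice, frozen after removal and extracted with Trizol, with libraries made with an Illumina TruSeq RNA kit and sequenced on an Illumina HiSeq instrument. They name 18 samples in 6 groups of 3, by gland (sublingual, submandibular, parotid) and sex. Whether the samples of a group came from separate animals is not given in the sources used here.

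The submitters' processing notes name STAR, Cufflinks and Cuffdiff and the mouse build mm10, without versions, roles or gene annotation. The deposited table has the layout of a Cuffdiff read group table, with 23281 gene symbols, 3 conditions and 6 numbered libraries in each, and status OK in every row. Estimated fragment counts per gene and library were deposited by the authors (expected counts, which need not be whole), and 96.8% of them were whole within 0.001. A scaled fragment signal was deposited by the authors beside them, which equals the estimated count multiplied by 1 factor per library. These factors ranged from 0.409 to 3.46 and lay within 0.521% of median-of-ratios factors computed here from the estimated counts. FPKM values were deposited by the authors per the file headers, and for a typical gene their ratio to the scaled signal varied by 0.204% between libraries (median coefficient of variation), so they carry the same factors. FPKM therefore does not sum to a constant (477488 to 2238609.9 per library), and a transcript that fills much of a library lowers the share of fragments of every other gene without lowering its FPKM in proportion. Strandedness of counting and filters applied before deposit are not given in the sources used here, so overlapping and antisense genes are uncertain.

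The 18 libraries of the table carry codes that match no title, description or other label, so all 18 unmatched libraries stayed outside every comparison between groups. Neither order nor measured values were used to assign them. The tests fixed before the data were examined (gland differences, sex differences, their interactions, gland-enriched genes and gene list tests) were for this reason not run, and no p-value is reported. Conditions A, B and C are the authors' own arrangement of the table, and whether they stand for glands was not assumed. Values are given as they stand in the table, as single libraries or as the median and range over the 6 libraries of a condition, except that the 6 values replace a median that moved by over 1.5 times when 1 library was left out. These libraries are not treated as replicates. No library was a copy of another: for each of the 153 pairs, the chi-square statistic per degree of freedom over genes with at least 20 fragments in the pair was 11.8 or more, where sampling noise alone gives about 1.

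The genes named followed a rule fixed before the data were examined, as far as it needs no group comparison: the 10 genes with the highest mean FPKM (here per condition of the table) and up to 3 members of each gene list with the highest mean FPKM over the 18 libraries, and every Y chromosome and X inactivation gene. Unnamed gene models and clone names were counted but not named. The rule gave 83 genes, and 23 more were chosen after their values were seen, as were the genes of the other observations that neither set holds. A first version of that added set held 32 genes and was shortened after it was known which values stood apart, so counts over all named genes depend on this choice and the counts of the 83 genes do not. The 23 gene lists were those of mucous cell and mucin, serous and parotid secretory proteins, kallikreins and granular convoluted tubule, secretoglobins, fluid and ion transport, secretagogue receptors and calcium signalling, endoplasmic reticulum and unfolded protein response, host defence, salivary transcription factors, steroid receptors and metabolism, Y chromosome and X inactivation, oxidative phosphorylation, proliferation, immune cells and lymph node, adipocyte, skeletal muscle, myoepithelial and basal cell, duct epithelium, endothelium, fibroblast and matrix, nerve and glia, lacrimal gland, and stress and handling. List members missing from the table were looked up by older symbols in the RefSeq gene table of GRCm38.p6, taking unique matches only. Gene coordinates are from GENCODE vM21 on GRCm38, the same build as mm10.

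Detection meant an FPKM of at least 1, in at least 3 libraries or as the median of a condition. Shares of fragments used the estimated counts, with 95% Wilson intervals for shares of single libraries. A count of 0 was read as under 3 fragments. To see whether a library stood apart from the other 5 of its condition, the gap of its value on the log2(FPKM + 1) scale, or of its library total or share, was compared with the range of the 6 values by Dixon's ratio. RNA of another kind in a library was estimated gene by gene from shares of fragments, with 30 genes abundant in the supposed source and under 5% of that level in the other libraries of the condition. On simulated data of 23281 genes, mixtures of 5% and 20% of the condition C profile in the condition A profile were estimated as 5.14% and 20.2%, and an unmixed library as 0.00892%. These mixtures were drawn from the same profiles that the estimate used, with counting noise only. They check the arithmetic and not the accuracy in real libraries. Real libraries of 1 condition differed by a chi-square per degree of freedom of 11.8 to 649. Median-of-ratios factors were recovered within 0.6% with 200 genes changed.

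Alternatives tried were median-of-ratios rescaling of the FPKM, quantile normalization, rescaling without the 50 most abundant genes, other detection filters (any value above 0, or a mean FPKM of at least 5) and, added after the data were seen, pseudocounts of 0.1 and 5, each library left out in turn, and libraries A5, B3 and B4 left out together. Analyses used Python 3.11.15 with pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9.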

Results

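RNA sequencing of salivary glands from C57BL/6J mice aged 12 weeks was described in the labels as 18 samples in 6 groups, the sublingual, submandibular and parotid glands of females and of males, with 3 samples in each group. The deposited table held 23281 genes in 18 libraries, arranged by the authors as 3 conditions of 6 libraries each. The library codes of that table occur in no sample label, so none of the 18 libraries was assigned to a gland or a sex. The conditions are named A, B and C here, in the order of the table, and the libraries A0 to A5, B0 to B5 and C0 to C5. The differences between glands and between sexes that the design poses were therefore not computed, and values are given per library or as the median of the 6 libraries of a condition with their range in parentheses. Where leaving out 1 library moved such a median by over 1.5 times, the 6 values are given in place of it. Estimated fragments per library ranged from 4410562 in A1 to 12624911 in B3, with a median of 10165826. At these depths, 3 fragments, the upper limit that a count of 0 allows, corresponded to 2.38e-05 to 6.80e-05% of fragments. Counting intervals and floors cover counting error only.

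A gene was detected at an FPKM (fragments per kilobase of transcript, scaled by library) of at least 1 in at least 3 libraries for 10304 genes. The median over the 6 libraries reached 1 FPKM for 8846 genes in condition A, 8844 in condition B and 8702 in condition C, and for 7904 genes in all 3 conditions. The 10 most abundant genes, Rn45s (the precursor of the ribosomal RNAs) included where it ranked among them, took 51.9% of fragments in condition A (median, range 44.6 to 77.0%), 42.2% in condition B (range 34.2 to 45.8%) and 80.6% in condition C (range 76.2 to 82.4%). With Rn45s left out of the ranking, the 10 most abundant genes took 51.9% (range 44.6 to 65.1%), 39.4% (range 31.3 to 42.7%) and 79.5% (range 76.0 to 82.4%) of fragments. The totals behind these shares still include Rn45s. Rn45s, named after its values were seen, took 0.253 to 13.7% of fragments. Its highest shares were 13.7% in A0 (95% Wilson interval 13.7 to 13.8%), 8.29% in A1 (8.27 to 8.32%), 8.03% in B2 (8.01 to 8.05%) and 5.25% in B3 (5.23 to 5.26%).

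**Figure D1:**
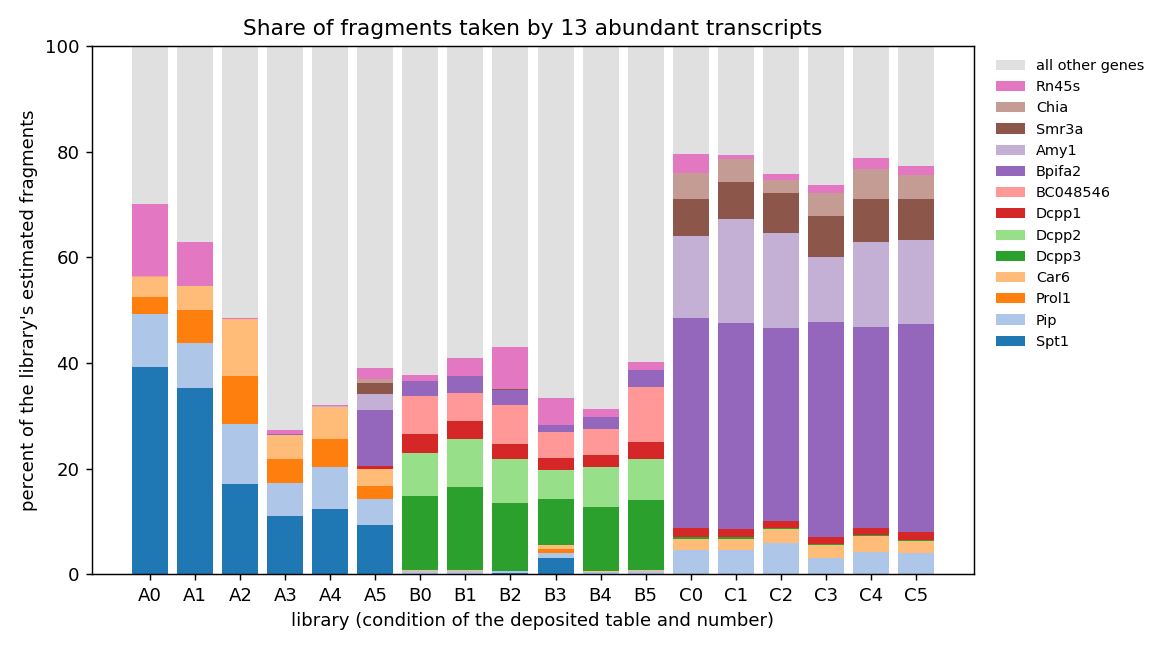
Stacked bars of the percent of each library's estimated fragments taken by 13 transcripts, for the 18 libraries on the horizontal axis, with all other genes in grey. Bpifa2 takes 36.5 to 40.7% in the 6 libraries of condition C, and Spt1 takes 39.2% in A0.

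By FPKM, each of the 6 libraries of condition A was led by Spt1, annotated today as Mucl2 and coding for a mucin-like salivary protein (chromosome 15, 103895855 to 103899312 in GENCODE vM21 on mm10). It took 14.7% (range 9.38 to 39.2%) of fragments, and the 6 libraries held FPKM of 1017240.0, 702464, 285173, 165999, 188347 and 146815 in the order A0 to A5. Pip, which codes for the prolactin-induced protein of saliva, took 8.24% (range 4.82 to 11.2%). Prol1, which codes for a proline-rich mucin of saliva, took 4.92% (range 2.50 to 9.17%), and Car6, the secreted carbonic anhydrase, took 4.67% (range 3.26 to 10.8%). Of the androgen-binding protein genes, median FPKM was 62764 (range 26884 to 108300.0) for Abpb and 38152 (range 19168 to 104177) for Abpa. For Abpg the 6 values were 30036, 48093, 31611, 9055, 13621 and 7965. Klk1, a tissue kallikrein, had a median FPKM of 8699 (range 7847 to 24364). For the kallikrein Klk1b26 the 6 values were 816, 1772, 4648, 73608, 56190.0 and 53386. Bpifa2 was among the 10 most abundant genes of condition A by mean FPKM because of A5 alone, where it reached 93669 and took 10.5% of fragments (95% Wilson interval 10.47 to 10.51%), a larger share than the 9.38% of Spt1. Its values in the other libraries lay between 41.5 and 137.

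In condition B, the highest median FPKM belonged to 3 genes of the demilune cell and parotid protein family. Dcpp3 (chromosome 17, 23917458 to 23919441) took 13.1% (range 8.81 to 15.8%) of fragments, Dcpp2 8.01% (range 5.48 to 9.14%) and Dcpp1 3.03% (range 2.34 to 3.52%). The clone-named gene BC048546, singled out after its values were seen, took 6.16% (range 4.79 to 10.5%), a larger share than Dcpp1 in each of the 6 libraries, at a lower FPKM of 6724 (range 4467 to 12608) against 37902 (range 23549 to 43492). Bpifa2 took 2.95% (range 1.29 to 3.20%). Nupr1, a stress-induced nuclear protein gene, had a median FPKM of 12446 (range 8084 to 18907), the secreted protease inhibitor gene Wfdc12 7859 (range 7046 to 9275) and Expi, annotated today as Wfdc18, 4066 (range 2609.9 to 6044). Pip stood at 8712 (range 4997 to 13244) and the ribosomal protein gene Rpl41 at 4653 (range 1926 to 5777). Spt1 entered the leading genes of this condition through B3, where its FPKM was 32572. The other B libraries ranged from 342 to 1703.

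In condition C, Bpifa2, a secreted BPI fold protein gene (chromosome 2, 154008265 to 154016079), took 39.1% (range 36.5 to 40.7%) of fragments. The salivary amylase gene Amy1 (chromosome 3, 113555710 to 113606699) took 15.9% (range 12.3 to 19.7%), the submaxillary gland androgen-regulated protein gene Smr3a 7.72% (range 7.02 to 8.21%), the acidic chitinase gene Chia 4.44% (range 2.45 to 5.75%) and Pip 4.27% (range 3.10 to 5.83%). Secreted enzymes and inhibitors made up most of the remaining leading genes. Car6 took 2.32% (range 2.17 to 3.07%), Dnase1, a secreted endonuclease, 1.64% (range 1.43 to 1.93%), Dcpp1 1.43% (range 1.33 to 1.62%), the cystatin gene Cst10 1.29% (range 1.13 to 1.60%) and Ggh, which codes for gamma-glutamyl hydrolase, 1.15% (range 0.933 to 1.47%). For Amy1, median FPKM was 197251 (109425 to 250730.0) in condition C and 30.7 (11.8 to 14352) in condition A, with the highest value of condition A in A5. B0 to B5 held 12.2, 32.6, 245, 52.2, 6.30 and 6.37.

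Among mucous cell and mucin genes, 20 of the 21 listed were in the table, and 7, 10 and 7 had a median FPKM of at least 1 in conditions A, B and C. Muc19, which codes for a gel-forming mucin (chromosome 15, 91838326 to 91934555), had a median FPKM of 407 (range 203 to 926) in condition B and 0.129 (0.0168 to 0.425) in condition C. A0 to A5 held 1.14, 0.111, 0.136, 0.0329, 0.0264 and 0.0450. Creb3l1, a transcription factor of secretory cells, had medians of 17.8 (12.9 to 39.7), 90.3 (74.1 to 119.6) and 22.4 (18.1 to 30.5) in conditions A, B and C. Agr2, a disulfide isomerase of mucous cells, had medians of 17.5 (8.95 to 38.8), 68.1 (56.1 to 96.5) and 0.546 (0 to 1.07). The gene Smgc, named after its values were seen, shares the start of this locus (chromosome 15, 91838265 to 91861438), so fragments of Muc19 and Smgc could be exchanged in the authors' estimates. Smgc had a median FPKM of 461 (range 335 to 725) in condition B and 0.327 (range 0.0420 to 2.55) in condition C. In A0 to A5 it held 425, 519.7, 1332, 0.0422, 0.0847 and 0.120.

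Of the 18 serous and parotid secretory proteins, all in the table, 13, 13 and 14 reached a median FPKM of 1 in conditions A, B and C. The examples with the highest mean FPKM were Bpifa2, Pip and Smr3a, and Smr3a had medians of 25.4 (5.02 to 29896), 25.5 (6.85 to 409) and 277402 (220881 to 319702). The proline-rich protein genes Prh1 and Prp2, named after their values were seen, stood out in C2, at FPKM of 244 and 24.1, and Prp2 was at 0 in the other C libraries. Kallikreins and genes of the granular convoluted tubule numbered 22 in the table, with 20, 15 and 19 at a median FPKM of 1 or more. Klk1b26 had medians of 9.97 (6.34 to 18637) in condition B and 29.2 (16.5 to 83.8) in condition C, and Klk1 of 455 (384 to 3001) and 1729 (1526 to 3026). In B3, Klk1b26 stood at 18637 and Klk1 at 3001. Of the 17 secretoglobins, 12 could be matched and 4, 3 and 2 reached a median FPKM of 1. Abpb, with medians of 62764 (26884 to 108300.0), 3653 (2174 to 6299.9) and 1957 (1366 to 3391), could be matched to no member by a unique older symbol and is outside these counts. Abpa had medians of 38152 (19168 to 104177), 1303 (739 to 5278) and 1108 (756 to 1903), and Abpg of 128 (18.1 to 1505) in condition B and 16.5 (7.17 to 280.3) in condition C. Abpz held 5.52, 9.78, 8.63, 1.76, 2.32 and 0 in A0 to A5, with medians of 0.643 (0.311 to 1.78) in condition B and 0 (0 to 1.14) in condition C. Members of the kallikrein, Dcpp, secretoglobin, amylase and Mup families share near-identical sequence, and the division of fragments within each family is uncertain.

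**Figure D2:**
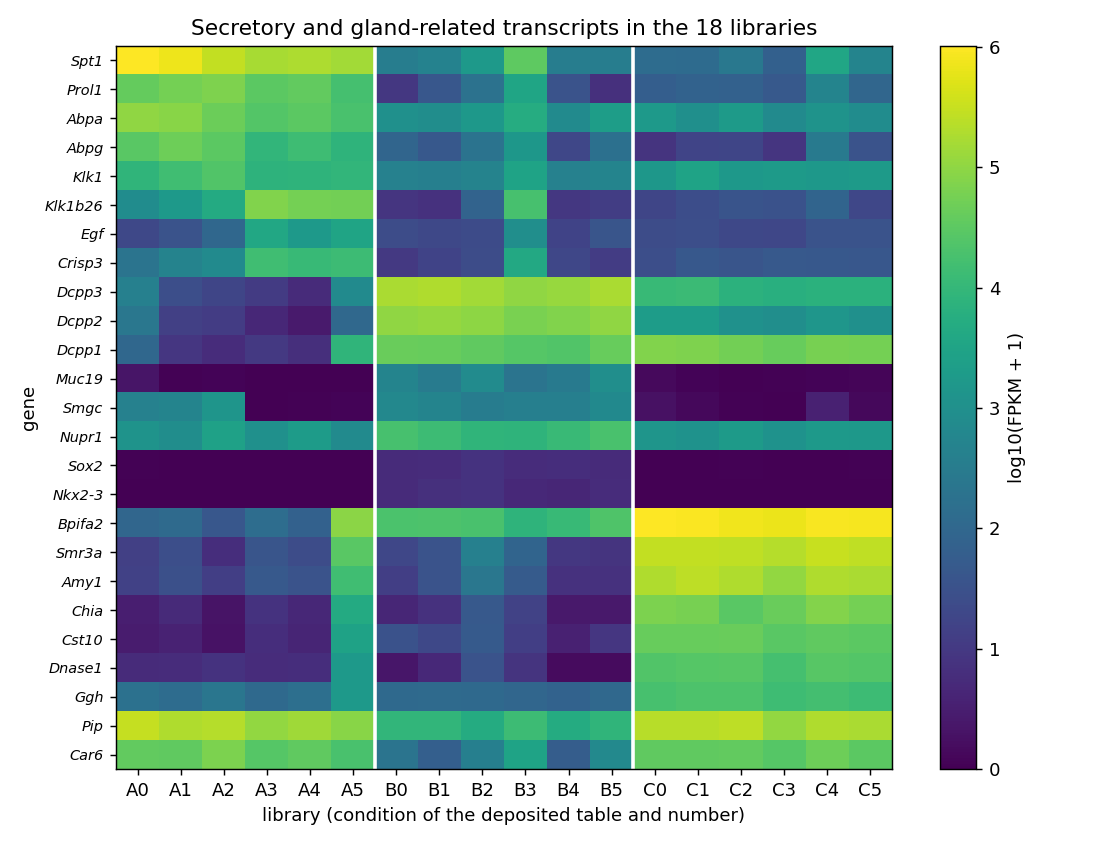
Heat map of log10(FPKM + 1) for 25 transcripts in rows and the 18 libraries in columns, with white lines between the conditions of the table. Amy1 and Bpifa2 stand high in condition C and in A5, at FPKM of 14352 and 93669, and Egf is at 947 in B3.

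Fluid and ion transport genes were all in the table (29), and 19, 15 and 17 had a median FPKM of at least 1 in conditions A, B and C. The sodium pump subunits Fxyd2 and Atp1b1 had medians of 1329 (699 to 2586) and 99.1 (81.5 to 208) in condition A, 302 (257 to 458) and 32.3 (26.4 to 56.4) in condition B, and 581 (461 to 1000.2) and 95.8 (83.4 to 139) in condition C. The water channel Aqp5 had medians of 52.4 (39.8 to 117), 82.7 (59.9 to 99.5) and 85.6 (64.5 to 132). The chloride entry and exit proteins Slc12a2 and Ano1, named after their values were seen, had medians of 55.1 (47.1 to 91.0) and 12.3 (9.94 to 13.6) in condition A, 43.1 (35.8 to 54.2) and 9.73 (6.75 to 12.0) in condition B, and 97.6 (62.6 to 108) and 27.9 (19.6 to 34.0) in condition C. Among the 25 secretagogue receptor and calcium signalling genes, 13, 13 and 14 reached a median FPKM of 1. The G protein subunit Gnas had medians of 137 (110.1 to 175), 127 (107 to 141) and 144 (125 to 206), the ATP-gated channel P2rx4 of 94.8 (44.5 to 105), 128 (111 to 215) and 126 (85.5 to 168), and Gnaq of 16.2 (9.21 to 29.2), 13.2 (11.7 to 18.5) and 12.9 (10.4 to 14.1). The muscarinic receptor Chrm3, named on the same basis, stood near the detection limit, with medians of 0.763 (0.586 to 0.866), 1.12 (0.723 to 1.64) and 1.43 (0.668 to 1.82).

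Genes of the endoplasmic reticulum and unfolded protein response were detected in every condition, with 24 of 25 at a median FPKM of 1 or more in each. Sec61a1, a subunit of the translocation channel, had medians of 164 (86.0 to 266), 266 (249 to 492) and 139 (98.5 to 202) in conditions A, B and C, Sec61b of 203 (95.3 to 327), 240.5 (207 to 360.2) and 262 (248 to 374), and Herpud1 of 145 (73.6 to 185), 153 (125 to 257) and 191 (172 to 274). For oxidative phosphorylation, 25 of 26 genes reached that level in each condition, led by Cox6c with medians of 1035 (776 to 1292), 639.8 (562 to 817) and 745 (582 to 831), Cox4i1 with 599 (506 to 771), 404 (310.1 to 486) and 617 (519 to 736), and Atp5o with 491 (414 to 713), 297 (219 to 369) and 457 (411 to 546).

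Host defence proteins numbered 22 in the table, and 12, 14 and 13 reached a median FPKM of 1 in conditions A, B and C. Beside Bpifa2, the highest mean FPKM belonged to Wfdc12 and Expi. Wfdc12 held 2114, 3216, 2873, 11799, 14528 and 8119.6 in A0 to A5, with medians of 7859 (7046 to 9275) in condition B and 4213 (3183 to 6210.2) in condition C. Expi had medians of 311 (269 to 555), 4066 (2609.9 to 6044) and 532 (378 to 1104). Of 30 salivary transcription factors, 20, 20 and 17 reached that level. Xbp1, a regulator of secretory capacity, had medians of 52.2 (36.1 to 109), 102 (77.4 to 227) and 96.2 (75.3 to 128), the epithelial factor Ehf 75.4 (31.3 to 109), 90.3 (66.5 to 132) and 58.9 (40.6 to 74.6), and Bhlha15 (Mist1), a factor of serous acinar cells, 42.3 (34.8 to 80.7), 18.8 (12.4 to 23.1) and 66.3 (53.6 to 98.7). Sox2 and Nkx2-3, named after their values were seen, had median FPKM of 4.83 (range 4.34 to 6.54) and 4.55 (range 3.43 to 6.55) in condition B. In the 12 libraries of conditions A and C, Nkx2-3 was at 0 and Sox2 was no higher than 0.0970. For steroid receptors and steroid metabolism, 21 of 22 genes were in the table and 7, 8 and 7 reached a median of 1. Hsd11b1 had medians of 51.9 (20.8 to 94.2), 7.11 (6.04 to 35.5) and 9.44 (6.11 to 21.6), Hsd17b4 of 42.5 (12.98 to 60.1), 14.0 (10.7 to 19.7) and 25.04 (22.0 to 32.6), and Comt of 20.5 (16.8 to 24.6), 25.5 (24.3 to 33.1) and 19.5 (15.7 to 22.7). The androgen receptor gene Ar, added after its values were seen, had medians of 2.54 (1.79 to 3.91), 0.315 (0.213 to 0.813) and 1.12 (0.451 to 1.31).

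Of 18 proliferation genes, 8 reached an FPKM of 1 in at least 3 libraries. Pcna had medians of 16.5 (12.5 to 20.2), 15.7 (9.90 to 18.7) and 14.2 (12.6 to 18.2) in conditions A, B and C, Mcm2 of 1.68 (1.19 to 2.45), 1.36 (1.04 to 1.78) and 1.68 (0.790 to 2.03), and Mcm6 of 1.18 (0.726 to 3.04), 1.71 (1.27 to 3.33) and 1.05 (0.774 to 1.86). Mki67, named after its values were seen, had medians of 0.268 (0.172 to 0.442), 0.210 (0.157 to 0.368) and 0.201 (0.106 to 0.239). The list of 5 Y chromosome and X inactivation genes had 4 members at an FPKM of 1 in at least 3 libraries. Highest values over the 18 libraries were 7.93 for Ddx3y, 13.9 for Eif2s3y, 3.12 for Uty, 0.929 for Kdm5d and 8.02 for Xist.

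Markers of other cell types differed between single libraries. All 24 immune cell and lymph node genes, once older symbols were matched, were in the table, and 8, 10 and 7 reached a median FPKM of 1 in conditions A, B and C. Cd74, the invariant chain of antigen presentation, had medians of 261 (189.8 to 429.6), 206 (141 to 1019.8) and 278 (187 to 427), with B4 the highest of condition B. Lyz2 of macrophages had medians of 87.4 (36.2 to 294), 121 (29.9 to 256) and 93.7 (51.1 to 377), and Cd52 of lymphocytes had medians of 34.9 (14.8 to 568) in condition B, highest in B4, and 34.1 (24.5 to 79.0) in condition C. A0 to A5 held 74.3, 66.5, 29.5, 15.6, 128 and 31.9. Of 15 adipocyte genes, 9 reached an FPKM of 1 in at least 3 libraries. Fabp4, Cfd and Car3 were highest in C2, at 699, 447 and 384. Their lowest values were 5.89 in A3, 0.0812 in A4 and 0.265 in A4. Of 16 skeletal muscle genes, 4 reached an FPKM of 1 in at least 3 libraries. Acta1, Tnnc2 and Ckm stood at 700.5, 437 and 402 in C5 and at 128, 124 and 75.5 in C2. In the other 16 libraries Acta1 reached at most 7.71, Tnnc2 at most 0.0764 and Ckm at most 5.69.

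**Figure D3:**
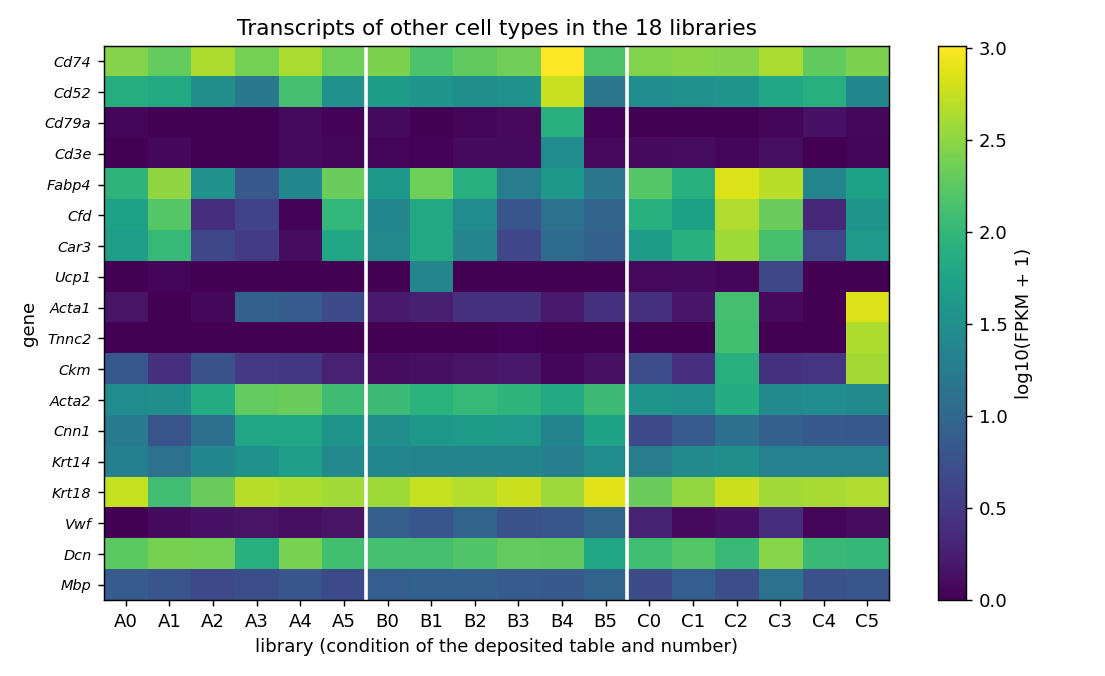
Heat map of log10(FPKM + 1) for 18 marker transcripts of other cell types in rows and the 18 libraries in columns, with white lines between the conditions of the table. Cd79a and Cd3e stand out in B4, at FPKM of 77.2 and 28.0, and Acta1, Tnnc2 and Ckm in C2 and C5.

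Myoepithelial and basal cell genes were seen throughout, with 9 of 10 at a median FPKM of 1 or more in each condition. Acta2 had medians of 94.2 (28.2 to 211), 95.8 (68.6 to 114) and 30.2 (25.6 to 72.5). Tagln held 30.7, 19.4, 28.8, 124, 119 and 86.5 and Cnn1 16.4, 5.09, 12.0, 59.8, 59.2 and 35.4 in A0 to A5. Their medians were 69.2 (49.8 to 80.6) and 40.1 (21.7 to 53.3) in condition B, and 17.0 (8.90 to 42.2) and 6.11 (3.75 to 11.5) in condition C. Of 15 duct epithelium genes, 14, 11 and 13 reached that level. Krt18 had medians of 413 (121 to 555), 517 (369 to 745) and 400.1 (206 to 581), Cldn10 of 344 (156 to 552), 442 (338 to 586) and 186 (135 to 225), and Krt8 of 73.0 (26.3 to 155), 93.1 (63.0 to 104) and 67.2 (53.0 to 115). These examples do not stand for the list. Krt7, Krt23, Ascl3, Foxi1, Atp6v1b1, Cftr, Slc9a3, Clcnkb and Tfcp2l1 had their highest median in condition A. Krt19, Kit and Elf5 had theirs in condition C. Endothelial genes reached a median FPKM of 1 for 3, 4 and 3 of 12 members. Vwf had medians of 0.340 (0.0507 to 0.448), 6.17 (4.64 to 8.27) and 0.321 (0.0856 to 1.49), Emcn of 2.98 (1.02 to 9.39), 1.06 (0.773 to 1.68) and 2.89 (1.66 to 4.44), and Esam of 2.02 (1.21 to 5.53), 1.61 (1.33 to 2.15) and 3.01 (2.48 to 5.50). Fibroblast and matrix genes reached it for 10, 11 and 11 of 13. Dcn had medians of 208 (75.3 to 251), 144 (57.6 to 190.0) and 115 (99.7 to 288), Sparc of 122 (75.4 to 186), 59.2 (46.6 to 126) and 72.8 (46.1 to 265), and Dpt of 8.90 (2.83 to 57.4), 13.2 (3.10 to 27.1) and 22.5 (7.39 to 90.4). Nerve and glia genes reached it for 4, 2 and 3 of 14. Mbp had medians of 4.66 (3.58 to 6.25), 7.20 (5.96 to 8.38) and 4.89 (4.03 to 12.6), Cnp of 3.28 (1.91 to 5.72), 6.46 (3.75 to 14.0) and 5.95 (3.28 to 8.38), and Gfra3 of 1.78 (0.883 to 3.29), 0.128 (0.0638 to 0.396) and 6.96 (5.64 to 9.03).

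For the lacrimal gland list, 11 of 12 genes were matched and 4, 3 and 4 reached a median FPKM of 1 in conditions A, B and C. Bglap-rs1, an older symbol of Bglap3, held 909, 902, 1419, 4329.5, 6394 and 3657 in A0 to A5, with medians of 789.7 (614 to 1220.5) in condition B and 1568 (1174 to 2348) in condition C. The major urinary protein genes Mup5 and Mup4 had medians of 572 (341 to 1387) and 0.808 (0 to 1.22) in condition A, and 549 (341 to 1237) and 0.584 (0 to 2.17) in condition C. In condition B, Mup4 had a median of 206 (164 to 277), and Mup5 held 3.09, 0.464, 30.9, 48.1, 2.34 and 7.30 in B0 to B5. The stress and handling list, a sign of how tissue was treated before lysis, had 19 genes in the table, of which 14, 12 and 14 reached a median of 1. Fosb, Junb, Hspa1a, Hspa1b and Socs3 stayed below that level in each condition, and Fos and Egr1 in condition B. The examples are the members with the highest mean FPKM and do not stand for the list. Btg2 had medians of 27.3 (15.03 to 35.6), 39.6 (29.0 to 45.4) and 30.4 (16.8 to 45.2), and Nr4a1 of 17.2 (12.6 to 36.3), 17.7 (12.3 to 27.5) and 42.0 (25.5 to 49.9). Ier3 held 11.4, 14.7, 11.5, 46.0, 40.9 and 40.3 in A0 to A5, with medians of 14.1 (10.7 to 15.4) in condition B and 11.1 (7.62 to 17.5) in condition C.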

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

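Values that stood apart from the other 5 libraries of their condition are given here as FPKM unless stated. Chance alone marks about 1 in 20 sets of 6 normal values. That rate does not hold where the 6 values fall into separate clusters, as for 47 genes of condition A described below. The range is then wide, and a library apart from its own cluster may go unmarked. Of the 249 sets of the genes named by rule (83 genes in 3 conditions), 23 stood apart, 7 of them in A5 and 4 in B3. This number was not held against the chance rate, since the rule picks genes by mean FPKM, which a single high library raises, and some sets lie near 0. The libraries A5, B3 and B4 were picked for a closer look after their values were seen, and the tests with single A libraries as the source of B3 were also chosen after values of B3 and of condition A were seen. RNA of another kind was not weighed in the other libraries. In B2, Smr3a (409), Amy1 (245), Chia (45.8), Dnase1 (33.6) and Cst10 (50.3) were the highest of condition B, and Bpifa2 and Ggh were not. In C4, Spt1 (3521), Prol1 (525) and Abpg (280) were the highest of condition C, and Abpa and Abpb were not. Bpifa2, Ggh, Abpa and Abpb cannot decide here, since a small share of such RNA could be hidden in the spread of their own levels. The 23 added genes were chosen after their values were seen too and were reduced from 32 once it was known which values stood apart. No biological explanation by gland or sex was tested, because no library was matched to a label, and lymphoid tissue was weighed only as RNA from other cells in a library.

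Library A5 held transcripts that lead condition C. Bpifa2 stood at 93669, Smr3a at 29896, Amy1 at 14352, Chia at 4650.2, Cst10 at 2881, Dnase1 at 1779.6 and Ggh at 1647. A whole condition C library under an A name was argued against, since 30 genes abundant in A0 to A4 and scarce in condition C had a median share in A5 that was 2.94 times their median in A0 to A4. That ratio does not measure how much of such RNA A5 kept, because A0 to A4 are themselves unequal. For a gene such as Klk1b26, the median of A0 to A4 is the low value of A2 (4648, against 53386 in A5). RNA of the kind in condition C may be present in A5: Amy1 would need it at 19.5% of fragments, and 30 other genes gave a median of 21.9% (quartiles 18.4 and 26.7%), a ratio of 1.12. Whether such RNA entered at dissection, extraction or sequencing was not tested.

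Library B3 held transcripts of condition A. Spt1 stood at 32572, Klk1b26 at 18637, Klk1 at 3001, Egf at 947, Ngf at 433, Crisp3 at 4129, Ren1 at 14.9, Muc13 at 10.6 and Lcn2 at 21.0. Whole replacement by a condition A library was argued against, since 30 genes abundant in the other B libraries and scarce in condition A had a median share in B3 of 0.687 times theirs. With the median condition A profile as the source, the planned ratio of 30 other genes to Egf was 0.597, inside the range of 0.5 to 2 set beforehand, but Egf then needed an impossible 148% of such RNA, so this test was left undecided, a reading chosen after the ratio was seen that replaced an earlier one in which the 148% alone excluded this source; Egf itself took 0.0076 to 2.86% of fragments in condition A. RNA like that of a single A library may be present: the ratios with A0 to A5 as the source were 0.00133, 0.0043, 0.0499, 0.929, 0.543 and 1.09, and 0.929 with A3, the nearest to 1 of the 6 tried, came from 31.3% for Egf and a median of 29.1% (quartiles 24.9 and 35.2%). Which library, and how such RNA entered, stays open.

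Library B4 held lymphocyte transcripts, with Cd74 at 1019.8, Cd52 at 568, Cd79a at 77.2 and Cd3e at 28.0. Over 8823 genes the median ratio of B4 to the median of the other B libraries was 0.931, so genes in general were not raised in B4. This ratio cannot weigh a scaling factor as the cause. The deposited factors lay within 0.521% of median-of-ratios factors, which hold the ratio of a typical gene near 1 in every library. Lymphoid tissue in the piece processed as B4 is a candidate explanation: of 23 further B and T cell genes whose values had not been looked at, 23 were highest in B4 among the B libraries, the most abundant being Cd37 at 48.9 and Cd2 at 39.0, and the median ratio to the next highest was 52.6 over the 21 with a value above 0 elsewhere (at least 3 in 20 of them, 1.15 for Ltb). Immune infiltration of the gland itself was not tested.

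Other values stood apart in single libraries, as the highest of their condition unless given as the lowest. In condition C these were Prol1 in C4 (525), Klk1 in C1 (3026), Dnase1 in C3 (16984, the lowest), Abpz in C5 (1.14, 2 fragments), Gnas in C0 (206), Acta2 in C2 (72.5), Esam in C3 (5.50), Crisp3 in C0 (26.1, the lowest), Ren1 in C5 (0.142, 1 fragment), Ucp1 in C3 (3.48), Slc12a2 in C3 (62.6, the lowest), and Prh1 and Prp2 in C2 (244 and 24.1). Condition B added Xbp1 and Ucp1 in B1 (227 and 22.7), Prh1 in B2 (0.688), Tnnc2 in B3 (0.0764, 1 fragment) and Dcn in B5 (57.6, the lowest). In condition A, Muc19, Prp2, BC048546 and Sox2 stood apart in A0 (1.14, 0.147, 20.1 and 0.0970) and Ucp1 in A1 (0.137, 1 fragment). A0 also held Dcpp2 at 246, the highest of condition A, and Dcpp3 at 422, above A1 to A4 and below the 767 of A5. Muc19, BC048546, Sox2, Dcpp2 and Dcpp3 had their highest medians in condition B. Whether A0 holds RNA of the kind in condition B was not weighed. The total of A1 was the lowest of its condition, at 4410562 fragments.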

How the results depend on the processing

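No paired analysis was possible because the library codes of the table match no replicate number in the labels, and no test between groups was run. Alternatives that need such a test (only the compared groups, robust variance, a replicate block, edgeR and DESeq2 fits, camera and fry settings, stricter q) were not run. The settings that left out single libraries, or A5, B3 and B4 together, and the pseudocounts were chosen after the data were seen.

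A shift was counted when a value moved by more than 1 SD between the 6 libraries, or a count by more than 1.5 times. The 10304 genes detected became 18158 with any value above 0 and 4426 with a mean FPKM of at least 5, by construction of the filter. With median-of-ratios rescaling, quantile normalization and rescaling without the 50 most abundant genes the count was 10299, 10315 and 10355. Quantile normalization sets the leading gene of every library to 341942 FPKM by construction, which moved Dcpp3 in condition B from its median of 164644 and Bpifa2 in condition C from 871558. Of the 318 medians of named genes per condition, quantile normalization moved 26 by more than 1 SD, mostly of the most abundant genes of conditions B and C. The other rescalings and leaving out libraries moved none. For leaving out 1 of 6 libraries this was fixed in advance, since such a median cannot move by more than 1 SD of the 6 values. Median-of-ratios rescaling could hardly move a median either, as the deposited factors already lay within 0.521% of it. A further 4 medians were 0 before and after, with no spread to judge them by. Leaving out 1 library moved 30, 12 and 12 of 101 medians above 0 in conditions A, B and C by over 1.5 times. Leaving out single libraries kept the detected genes between 10223 and 10282, the median FPKM of Spt1 in condition A between 188347 and 285173, and the share of the 10 leading genes there between 45.5 and 58.3%. Without A5, B3 and B4, 10150 genes were detected. The number of values that stood apart was 43 and became 42 and 50 with pseudocounts of 0.1 and 5.

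Counts of list members with a median FPKM of 1 or more kept within 1.5 times under the 3 rescalings. Leaving out A0, A1 or A5 took the adipocyte list in condition A from 8 to 5, and leaving out B3 and B4 together took the proliferation list in condition B from 5 to 3. Counts of the skeletal muscle and of the Y chromosome and X inactivation lists rest on few libraries and are not given as medians. Genes near 1 FPKM rest on the fewest fragments in C1 and C0, whose scaling factors are the largest (3.46 and 3.20, against 2.18 in A1). In the shallowest library, A1, 3 fragments are 6.80e-05% of the library.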

Other observations

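Within condition A, 58 genes had a gap of at least 2 on the log2(FPKM + 1) scale between the 3 lower and the 3 higher of their 6 values. For 47 of them the gap lay between A0 to A2 and A3 to A5, which is 1 of 10 ways to divide 6 libraries into 3 and 3, and for 10 it set A0, A1 and A5 apart from A2 to A4. The genes named here were chosen after their values were seen, except those of the sex chromosomes, Acta2, Tagln, Cnn1, Ier3, Btg2, Nr4a1, Fabp4 and Spt1. Condition B had 2 such genes and condition C 8. Of the 22 kallikrein and granular convoluted tubule genes in the table, 18 were among these 47, a count that was not tested and is not one of separate observations, since kallikreins share near-identical sequence. Of the myoepithelial and basal cell list, 0 of 10 genes were among these 47, and of the stress and handling list 0 of 19. Some members held unequal values over the same libraries below that gap, with Acta2 at 28.2, 30.4, 69.2, 192, 211 and 119, Tagln at 30.7, 19.4, 28.8, 124, 119 and 86.5, Cnn1 at 16.4, 5.09, 12.0, 59.8, 59.2 and 35.4 and, for handling, Ier3 at 11.4, 14.7, 11.5, 46.0, 40.9 and 40.3 in A0 to A5. Other members showed no such division in condition A. Leaving out 1 library kept the median of Btg2 between 26.4 and 28.2, of Nr4a1 between 15.6 and 18.8 and of Krt14 between 23.9 and 25.3. Egf, the epidermal growth factor gene (chromosome 3, 129677565 to 129755316), held FPKM of 18.7, 32.9, 99.1, 4101, 1693 and 3176 in A0 to A5, and Ngf, the nerve growth factor gene, 12.4, 27.1, 37.1, 2048, 1420.2 and 1395. Crisp3 held 209, 485, 767, 14821, 11210.2 and 12865, Ren1, the renin gene, 4.14e-05, 0.162, 2.87, 66.6, 36.7 and 36.6, and Lcn2 11.5, 2.12, 3.65, 129, 56.1 and 52.3. Crisp1 held 0.722, 1.79, 1.90, 429.8, 259 and 791. The estrogen sulfotransferase gene Sult1e1 held 0, 0.373, 0.192, 99.9, 76.2 and 93.0, and the cytochrome P450 gene Cyp2b10 held 0.655, 1.54, 4.21, 132, 122 and 87.3. The neurotrophin receptor gene Ngfr held 2.93, 1.54, 0.948, 53.8, 21.2 and 30.4. Smgc ran the other way, with 425, 519.7, 1332, 0.0422, 0.0847 and 0.120, and so did the sialyltransferase gene St3gal1, with 34.4, 40.6, 76.8, 7.27, 3.84 and 3.16. Egf in the B and C libraries other than B3 lay between 14.8 and 36.4.

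Genes of the sex chromosomes divided libraries 0 to 2 from libraries 3 to 5 in each condition. In condition A this is the same division as that of the 47 genes above, of which Eif2s3y is 1. Xist held 2.64, 8.02, 2.44, 0.00573, 0.00977 and 0.00981 in A0 to A5, 2.32, 1.68, 2.06, 0, 0.00404 and 0.0115 in B0 to B5 and 3.10, 2.62, 1.91, 0, 0 and 0 in C0 to C5. The Y-linked gene Eif2s3y held 0.279, 0, 0, 9.59, 13.5 and 8.53, 0.0398, 0, 0.0364, 8.68, 13.9 and 11.6, and 0, 0, 0, 8.25, 10.03 and 8.97. Ddx3y held 0.517, 0, 0.0152, 5.48, 4.44 and 5.08, 0.0280, 0, 0, 4.74, 6.33 and 7.93, and 0, 0, 0, 4.62, 3.29 and 4.67. Uty held 0.0652, 0, 0, 1.65, 1.51 and 1.51, 0.0124, 0, 0, 2.45, 2.55 and 3.12, and 0, 0, 0, 1.37, 1.52 and 1.42, and Kdm5d 0.0622, 0, 0, 0.755, 0.6252 and 0.735, 0, 0, 0, 0.785, 0.845 and 0.702, and 0, 0, 0, 0.929, 0.811 and 0.859. A0 carried 21 fragments of Ddx3y, 4 of Eif2s3y, 3 of Uty and 3 of Kdm5d beside 427 of Xist. The labels list 9 female and 9 male samples, and these values were not used to assign any library.

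Adipocyte genes varied from library to library. Fabp4 held 89.2, 324, 32.4, 5.89, 23.4 and 206 in A0 to A5, 39.1, 222, 78.5, 18.1, 38.8 and 14.5 in B0 to B5 and 165, 76.1, 699, 496, 22.6 and 51.5 in C0 to C5, and Adipoq held 8.09, 19.0, 0.592, 0.284, 0 and 14.3 in A0 to A5. Ucp1, a gene of brown adipocytes, had 630 fragments in B1 and 43 in C3 and at most 1 in each of the other 16 libraries. Igj, the immunoglobulin joining chain gene annotated today as Jchain, held 11.6, 0.136, 0.902, 6.00, 26.5 and 0.771 in B0 to B5. C4 held Spt1 at 3521 and C5 at 522, while C0 to C3 lay between 67.9 and 257.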
